A study of Mus musculus with 3 samples.

How the data were processed

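Chromatin accessibility was measured by ATAC-seq in mouse skin squamous cell carcinomas induced with DMBA and TPA, a mutagen followed by a tumour promoter. Tumour cells carrying a YFP reporter switched on by keratin 14 Cre were sorted by the epithelial surface protein Epcam. The labels name 3 libraries, 1 per group: Epcam+ cells of a control tumour (control Epcam+), Epcam+ cells of a tumour with conditional Fat1 deletion (Fat1 cKO Epcam+), and Epcam- cells of a tumour with the same tumour label (Fat1 cKO Epcam-). Per the labels' protocols, 100000 sorted cells were lysed and their nuclei incubated with Tn5 transposase for 30 minutes at 37 degrees, and fragments of 200 to 800 bp were selected.

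The authors deposited 1 table of raw counts over 95842 merged regions, with a count column and a yes or no peak-call column for each library. Bowtie2 2.2.6, SAMtools, Picard, MACS2 2.1.0.20151222 and the build mm10 (GRCm38) are named in the submitters' processing notes, with no role or order. Whether reads or fragments were counted, the counting tool, the filters, any shift for Tn5 binding and the threshold of the peak calls are not given in the sources used here. The deposited peak calls (other values, yes or no) were used only to describe regions and to compare them with the counts. A shift of read ends by a few bases would move few counts between regions of this width (median 642 bp, range 203 to 8457 bp).

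Columns were assigned to libraries by their names, which equal the sample titles. Because the peak calls and the counts of 2 libraries disagree, as described below, the text writes "the library labelled" before each name, and each direction is a direction between column names.

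The 2 mitochondrial regions were left out, leaving 95840. Nuclear counts were 4335304 in the library labelled control Epcam+, 3812880 in that labelled Fat1 cKO Epcam+ and 5485317 in that labelled Fat1 cKO Epcam-. Effective library sizes came from TMM factors of edgeR 4.0.16 in R 4.3.3 (1.04, 0.959 and 1.00 in that order). CPM values, counts scaled to an effective library size of 1000000, and log2 ratios were computed in Python 3.11.15 with edgeR's formula and a prior count of 2. A region passed the size rule at 2-fold or more with at least 20 counts in 1 of the 2 libraries. With 1 library per group there are no replicates, no test between conditions and no p-values. Intervals are 95% Clopper-Pearson intervals of a ratio, or exact Poisson intervals of a count. They cover counting error only, since each group has 1 library. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow and the simulated numbers below too low. The number of regions that counting error alone would put past the size rule was simulated 20 times per pair from Poisson counts with no difference. A count of 0 was read as up to 3 counts, which is 0.666, 0.820 and 0.545 CPM in the 3 libraries in the order above. Folds given for such regions use 3 counts and take the other count as exact, so the interval reaches smaller folds.

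Gene positions came from a RefSeq gene table of the same build, GRCm38, which gives no strand. The planned nearest transcription start could therefore not be used. Each region was assigned instead to the protein-coding gene whose body lay nearest to the region's midpoint, within 50 kb. This gave 79134 regions (82.6%) a gene, among them 52260 inside a gene body. "Near a gene end" means within 1 kb of either end of a gene, which held for 13578 regions (14.2%). Motif shares and the correction for GC content were not run, since both need the genome sequence, not used here.

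Gene counts are sums over assigned regions, and a gene needed 20 counts in 1 of the 2 libraries. The size of a gene's ratio depends on which regions are assigned to it: 39 of the 131 ratios described below moved by over 1.5 times under another way of assigning or combining them. The 18 gene lists, with 309 symbols, all found in the gene table, were fixed before the data were examined, together with the size rule, the comparisons and all but 5 of the alternatives. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on deciles of mean log2 CPM. It describes these libraries and is not a p-value. The lists hold epithelial genes, mesenchymal and EMT genes, squamous differentiation genes, hair follicle stem cell genes, YAP/TAZ targets, tumour stemness genes, AP-1 subunits, the TGF-beta and BMP pathway, surface markers of EMT tumour cells, kinases and chromatin regulators, Fat cadherins, housekeeping genes, and markers of immune cells, endothelial cells, fibroblasts and pericytes, melanocytes, skeletal muscle and adipocytes.

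Genes to be named were set by a rule fixed at the same time: Fat1 first; per pair the 10 higher and 10 lower genes with the largest log2 ratio among those with at least 100 counts in 1 library and at least 2 regions, leaving out unnamed models; per list up to 4 highest and 4 lowest members; the 3 highest and 3 lowest regions; and Epcam, Vim, Zeb1, Sox2, Cd44 and Trp63. The rule gives 465 combinations of gene and pair. Some of these are not reported here. The 131 described in the text were picked from these after their values were seen, with a preference for genes that kept their sign under the alternatives, so they are not a sample of how stable the genes are.

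The size rule was tested on simulated data with the real library sizes and 200 changed regions among 95840. For the library labelled Fat1 cKO Epcam+ over that labelled control Epcam+, it recovered 95.0% of regions changed 2.5-fold and 2.0% of those changed 1.5-fold. For the library labelled Fat1 cKO Epcam- over that labelled Fat1 cKO Epcam+, the shares were 91.5% and 1.5%. For the library labelled Fat1 cKO Epcam- over that labelled control Epcam+, they were 91.5% and 3.0%. These regions had 30 or more expected counts in each library, so recovery is lower where counts are lower.

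Alternatives covered scaling (total counts, DESeq2 1.42.0 size factors, regions near gene ends, a trend over mean signal, the median of each chromosome), the count minimum, the fold, the prior count, leaving out X and Y, and how regions are assigned to genes. Added after the data were seen were the exchange of 2 count column names, thinning to the smallest depth, called regions only, assignment by the nearest gene end, and shared regions taken only from those with enough counts in both ratios. That last share was computed first. It was then replaced by the planned one, over all regions past the size rule in the third pair, because it depends on the joint count minimum.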

Results

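ATAC-seq counts were available for 3 libraries of sorted mouse skin squamous cell carcinoma cells, with 1 library in each of 3 groups and no replicates. Each library's counts cover the same merged regions of the mm10 build. Total counts were 7122115 in the library labelled control Epcam+, 6647179 in that labelled Fat1 cKO Epcam+ and 9304031 in that labelled Fat1 cKO Epcam-. Without the mitochondrial regions, 4335304, 3812880 and 5485317 counts remained. Peaks were called by the authors in 54716, 40714 and 47606 regions in the same order, 25769 of them in all 3 libraries, and 19942 regions (20.8%) were called in none.

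Fat1, the protocadherin gene targeted by the conditional allele, kept counts in each of the 3 libraries. The gene lies on chromosome 8 from 44933100 to 45052257, and its 20 assigned regions summed to 158 CPM in the library labelled control Epcam+, 191 CPM in that labelled Fat1 cKO Epcam+ and 249 CPM in that labelled Fat1 cKO Epcam-. None of the 15 regions within 5 kb of the gene was at 0 in any library. The region from 45001427 to 45002054, inside the gene body, held 57, 14 and 49 counts in the same order. A second region inside the gene, from 45018636 to 45019488, held 14, 2 and 14 counts. These 2 regions were singled out after their values were seen. Which exons the conditional allele removes is not given in the sources used here, and accessibility does not measure the transcript, so these counts check no label.

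Epcam, the surface protein the cells were sorted on, ran against the column names in 1 of the 2 pairs of an Epcam- and an Epcam+ library. Its 6 assigned regions summed to 67.7 CPM in the library labelled control Epcam+, 224 CPM in that labelled Fat1 cKO Epcam+ and 132 CPM in that labelled Fat1 cKO Epcam-. The library labelled Fat1 cKO Epcam- was thus above that labelled control Epcam+, with a log2 ratio of 0.96 (95% interval 0.77 to 1.16), and below that labelled Fat1 cKO Epcam+, with one of -0.76 (-0.91 to -0.62), which turns to 0.09 over regions near its gene ends. At the region over one end of the gene, chromosome 17 from 87635827 to 87637328, the counts were 69 in the library labelled control Epcam+, 205 in that labelled Fat1 cKO Epcam+ and 328 in that labelled Fat1 cKO Epcam-. This region was singled out after its values were seen.

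The authors' peak calls and counts also disagreed for the same 2 libraries. In the 18422 regions called as peaks only in the library labelled control Epcam+, the median count was 9 (2.0 CPM) in its own count column and 29 (5.27 CPM) in the column labelled Fat1 cKO Epcam-. In the 10758 regions called only in the library labelled Fat1 cKO Epcam-, the median was 10 (1.82 CPM) in its own column and 25 (5.55 CPM) in the column labelled control Epcam+. The 5353 regions called only in the library labelled Fat1 cKO Epcam+ were highest in its own column, at a median of 24 counts (6.56 CPM). Directions below are between column names, and each comparison states what it would be if the names of these 2 count columns were exchanged.

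**Figure D1:**
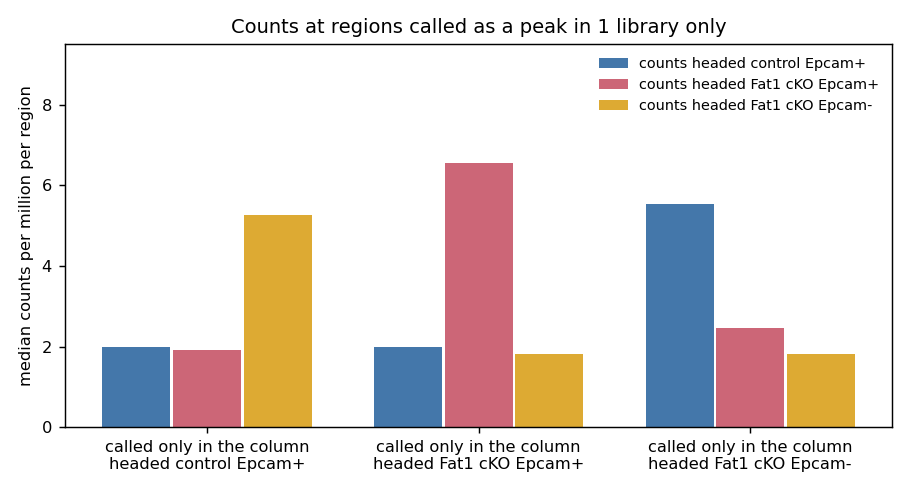
Median CPM (vertical axis, bars) at regions called as a peak in 1 library only, grouped by the name of the peak-call column and coloured by the name of the count column. Regions called only in the column headed control Epcam+ have 5.27 CPM in the counts headed Fat1 cKO Epcam- and 2.0 CPM in the counts headed control Epcam+.

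The Y chromosome separated the same library from the other 2. Its 33 regions held 1196 counts (217 CPM, exact Poisson interval 205 to 230) in the library labelled Fat1 cKO Epcam-, against 218 (59.6 CPM, 52.0 to 68.1) in that labelled Fat1 cKO Epcam+ and 339 (75.2 CPM, 67.4 to 83.6) in that labelled control Epcam+. In 16 of the Y regions the library labelled Fat1 cKO Epcam- had 10 or more counts and both others had 0 or 1. The titles of the libraries labelled Fat1 cKO Epcam+ and Fat1 cKO Epcam- name the same tumour.

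The first comparison asked how Epcam+ tumour cells differ with Fat1 deletion, and set the library labelled Fat1 cKO Epcam+ over the library labelled control Epcam+. Epithelial genes were more accessible in the library labelled Fat1 cKO Epcam+. Of 45 epithelial genes 30 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.56, percentile 100 among random lists. Krt6a, a stress keratin of wounded epidermis, was 6.98-fold higher (log2 ratio 2.80, 95% interval 2.42 to 3.30). Krt14 and Krt5, the paired keratins of basal keratinocytes, were 5.37-fold and 5.07-fold higher. Grhl1 and Cldn1 were near even, with log2 ratios of -0.01 (-0.20 to 0.18) and 0.16 (-0.10 to 0.43).

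Squamous differentiation genes were higher in the same library. Of 18 measured members 9 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.07 (percentile 100). Sprr1a, a precursor of the cornified envelope, was 6.28-fold higher, Krt16 5.33-fold higher, and Tgm1, the transglutaminase that crosslinks that envelope, 4.85-fold higher. Sprr1a and Krt16 rest on 1 region each.

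Mesenchymal and EMT genes were lower in the library labelled Fat1 cKO Epcam+. Of 40 genes 7 were at least 2-fold lower and 1 at least 2-fold higher, with a median log2 ratio of -0.26 (percentile 0). The collagen gene Col3a1 was 4.65-fold lower (log2 ratio -2.22, -2.83 to -1.75), the metalloproteinase gene Mmp19 2.94-fold lower, Col1a2 2.35-fold lower and the transcription factor gene Prrx1 2.26-fold lower. Cdh2, which encodes N-cadherin, was the member at least 2-fold higher, at 2.06-fold. Over regions near gene ends Cdh2 and Col1a2 were under 2-fold, at log2 ratios of 0.59 and -0.78. Vim stood at 103 CPM in the library labelled control Epcam+ and 89.1 CPM in that labelled Fat1 cKO Epcam+, and Zeb1, a repressor of epithelial genes, at 190 and 129 CPM.

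Epcam was 3.30-fold higher in the library labelled Fat1 cKO Epcam+ (log2 ratio 1.72, 1.54 to 1.92), and Trp63, the p63 gene of stratified epithelia, 1.87-fold higher (0.90, 0.70 to 1.11). Sox2, a stem cell transcription factor gene, was 3.36-fold lower (-1.75, -2.08 to -1.46), and Cd44 stood at -0.36 (-0.48 to -0.24). Within the tumour stemness list Sox2 and Pitx1 went opposite ways, Pitx1 at 3.48-fold higher, and the list's median was 0.18 (percentile 77.4). Pitx1 had a log2 ratio of only 0.75 over regions within 10 kb. Bmp7 was 4.13-fold higher and was the 1 member of the TGF-beta and BMP pathway at least 2-fold apart, with a list median of 0.07. Among the Fat cadherins, Fat3 and Fat2 were 3.29-fold and 2.92-fold higher, and the list of 4 had a median of 0.91 (percentile 99.8). The bootstrap interval of that median over members was -0.48 to 1.72. Fat4 was lower, at 26.5 CPM against 37.3 CPM in the library labelled control Epcam+. Fat3 had a log2 ratio of 1.00 over regions near its gene ends. Surface markers of EMT tumour cells had a median of -0.29 (percentile 0.48), with Vcam1, an adhesion receptor, 2.30-fold lower, but the median was 0.13 over regions near gene ends.

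YAP/TAZ targets had a median of 0.03 and AP-1 subunits one of 0.29, and 0 members of either list were 2-fold apart. Hair follicle stem cell genes stood at 0.28, kinases and chromatin regulators at 0.13, where Tead3 was 2.14-fold higher, and housekeeping genes at 0.15. These 5 medians lay within the middle 95% of random lists. So did the markers of other cell types: 0.01 for immune cells, -0.00 for endothelial cells, -0.15 for fibroblasts and pericytes, 0.35 for melanocytes, 0.38 for skeletal muscle and 0.07 for adipocytes. Single markers went both ways, with Meox2 4.34-fold higher, Pi16 4.79-fold lower, Kdr 2.25-fold lower and Itgax 2.08-fold lower. Pi16 rests on 5 against 37 counts. Over regions near gene ends Meox2, Kdr and Tead3 were under 2-fold, at log2 ratios of 0.89, -0.90 and 0.77.

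Among the 10 higher and 10 lower genes with the largest differences, not all of which are named, the zinc transporter gene Slc39a4 was 9.46-fold higher in the library labelled Fat1 cKO Epcam+, the tight junction gene Ildr1 8.49-fold, the mucin gene Muc16 8.0-fold, Mmrn2 6.41-fold and the myosin gene Myh14 6.04-fold. Zscan4c was 10.9-fold higher, but it belongs to a family of near-identical copies, so its reads are uncertain. Lower were Stc2 (5.79-fold), the prostacyclin receptor gene Ptgir (5.17-fold), Irx6 (5.02-fold), the potassium channel gene Kcna5 (4.98-fold) and Sall1 (4.96-fold). A region 26918 bp from Nfib, chromosome 4 from 82263037 to 82263473, held 48 counts against 1 (log2 ratio 4.36, 3.34 to 11.22). Inside Ppfibp1, the region on chromosome 6 from 146970929 to 146971283 held 31 counts against 0. That is 12.7-fold higher with the 0 read as described above, and the log2 interval starts at 3.29. Inside Sipa1l2, chromosome 8 from 125498385 to 125498861, the counts were 0 against 75. With the same reading of the 0 that is 20.3-fold lower, and the log2 interval ends at -4.01.

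Over all regions, 53678 had enough counts in this pair, of which 10072 were at least 2-fold higher in the library labelled Fat1 cKO Epcam+ and 8763 at least 2-fold lower. Counting error alone would put 223 and 427 there. With total-count scaling in place of TMM, the ratios of this pair fall by 0.11 on the log2 scale. If the 2 count column names were exchanged, the same ratios would set Fat1 cKO Epcam+ over Fat1 cKO Epcam- cells.

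**Figure D2:**
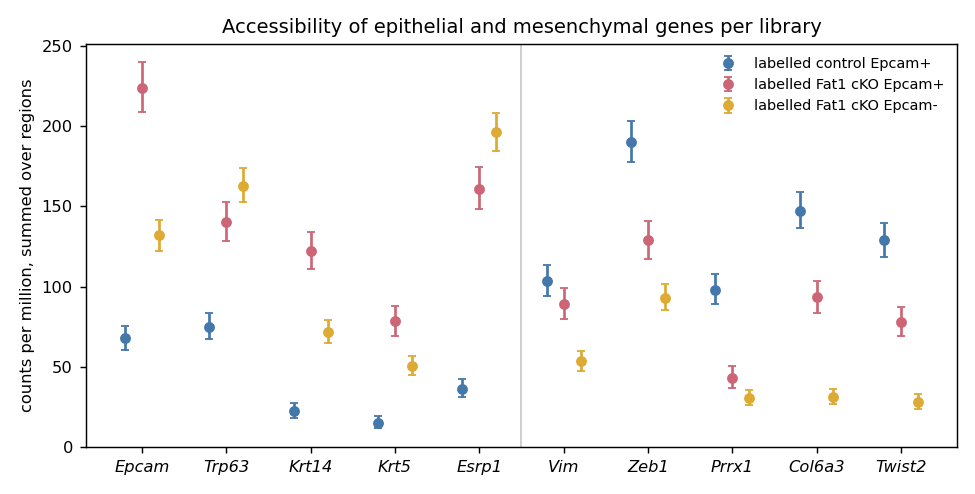
CPM summed over the regions of 10 genes (vertical axis) in each library (colours), with exact Poisson 95% intervals as bars. Epithelial genes stand left of the grey line and mesenchymal genes right of it; Epcam has 67.7 CPM in the library labelled control Epcam+ and 224 CPM in that labelled Fat1 cKO Epcam+, and Prrx1 98.0 and 43.2 CPM.

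In the second comparison, on how Epcam- differ from Epcam+ cells of Fat1-deleted tumours, the library labelled Fat1 cKO Epcam- was set over that labelled Fat1 cKO Epcam+. Mesenchymal and EMT genes were less accessible in the library labelled Fat1 cKO Epcam-. Of 40 genes 13 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -0.65 (percentile 0). The collagen genes Col6a2, Col6a3 and Col1a2 were 3.89-fold, 2.97-fold and 2.76-fold lower (Col6a2 log2 ratio -1.96, -2.33 to -1.65, but -0.76 over regions within 10 kb). Lum was 4.07-fold lower on 10 against 32 counts, and Twist1 2.03-fold lower, but under 2-fold under at least 1 alternative. Vim stood at 53.5 against 89.1 CPM, Zeb1 at 93.1 against 129 CPM, and Acta2, the smooth muscle actin gene, at 30.7 against 19.1 CPM.

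Epithelial genes were even in this pair, with a median log2 ratio of 0.02 (percentile 87.5) over 45 genes. Among them 2 were at least 2-fold higher, the transcription factor genes Ovol1 (2.33-fold) and Tfap2c (2.01-fold). Both fell under 2-fold in an alternative. Ovol1 had a log2 ratio of 0.23 over regions near its gene ends, and Tfap2c 0.45 with the median of each chromosome set to 0. The 4 at least 2-fold lower were Krt18 and Krt8, the paired keratins of simple epithelia, at 3.58-fold and 3.18-fold, the claudin gene Cldn7 at 3.49-fold and the laminin gene Lamb3 at 2.17-fold. Epcam had a log2 ratio of -0.76 (-0.91 to -0.62) over its assigned regions, but 0.09 over those near its gene ends and also over those within 10 kb. Trp63 and Cd44 each stood at 0.22, and both fall below 0 when the median of each chromosome is set to 0, at -0.08 and -0.33. Cd44 also falls below 0 over regions near gene ends, at -0.04.

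Squamous differentiation genes had a median of 0.16 (percentile 82.4) with 3 of 18 at least 2-fold higher, among them Tgm3 (4.53-fold) and Casp14 (4.35-fold), both of cornifying cells. Bmp4 was 6.57-fold higher (2.71, 2.27 to 3.31) and Bmp2 2.76-fold higher, while Ltbp2, which binds the extracellular matrix, was 2.80-fold lower. The TGF-beta and BMP list had a median of -0.02. Lhx2 and Cd34, markers of hair follicle stem cells, were 2.83-fold and 2.44-fold higher, with a list median of -0.08. Itgb3, the integrin beta 3 gene, was 3.13-fold lower, the TEAD factor gene Tead1 2.05-fold lower and Hmga2 2.34-fold lower, and Sox2 was 1.63-fold higher (0.70, 0.38 to 1.05). Cd34 fell to a log2 ratio of 0.94 as a median over its regions, and Ltbp2 to -0.94 over regions near its gene ends.

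Within the YAP/TAZ targets Fjx1 was 3.40-fold higher and Arhgef17 2.30-fold lower, and the list's median was -0.15. Medians were -0.12 for tumour stemness, -0.17 for AP-1 subunits, 0.01 for surface markers of EMT tumour cells, -0.18 for kinases and chromatin regulators, -0.24 for housekeeping genes and 0.20 for Fat cadherins, where Fat3 was 1.95-fold lower. The TGF-beta and BMP, hair follicle and YAP/TAZ medians and these 6 lay within the middle 95% of random lists. Immune cell markers had a median of -0.49 (percentile 1.15) over 12 measured genes, none 2-fold apart. Fibroblast and pericyte markers had one of -0.63 (percentile 0.21), with Rgs5 3.38-fold lower, but 0.27 over regions near gene ends. Rgs5 itself had a log2 ratio of -0.47 over those regions. Endothelial markers stood at 0.39 (percentile 95), Tie1 at 2.66-fold higher, and melanocyte, skeletal muscle and adipocyte markers at -0.19, -0.19 and 0.40, within the random range.

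The 10 genes with the largest differences on the higher side included the claudin gene Cldn17 (9.16-fold), Ttpa (8.89-fold), the monocarboxylate transporter gene Slc16a7 (7.94-fold), the sphingolipid synthesis gene Sptlc3 (7.92-fold, but a log2 ratio of 1.21 over regions near its gene ends), Dach1 (7.01-fold) and Kcnc4 (6.98-fold). The 10 on the lower side included Slc13a1 (10.9-fold), Foxa3 (8.86-fold), Slc39a4 (7.91-fold) and the glutamate receptor gene Gria1 (6.25-fold). Zscan4c and Ifi204 were 34.6-fold and 16.4-fold lower, and both are in families of similar copies, which leaves their reads uncertain. At Eif2s3y, chromosome Y from 1010110 to 1010797, the counts were 82 against 0. That is 18.2-fold higher with the 0 read as described above, and the log2 interval starts at 3.85. Inside Zfp568, chromosome 7 from 30009490 to 30010991, the counts were 3 against 197 (log2 ratio -5.79, -8.92 to -5.06). In Trim12a, chromosome 7 from 104314697 to 104316044, they were 0 against 65. With the same reading of the 0 that is 32.6-fold lower, and the log2 interval ends at -4.69.

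This pair had 62308 regions with enough counts, 15597 of them at least 2-fold higher in the library labelled Fat1 cKO Epcam- and 10876 at least 2-fold lower, against 570 and 169 from counting error alone. If the 2 count column names were exchanged, these ratios would set control Epcam+ over Fat1 cKO Epcam+ cells, that is, the inverse of the genotype comparison.

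The third comparison set the library labelled Fat1 cKO Epcam- over that labelled control Epcam+. Epithelial genes were more accessible and mesenchymal genes less accessible in the library labelled Fat1 cKO Epcam-. Of 45 epithelial genes 28 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.30 (percentile 100). Of 40 mesenchymal and EMT genes 19 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.94 (percentile 0). Squamous differentiation genes had a median of 1.79 (percentile 100), with 15 of 18 at least 2-fold higher.

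Esrp1, an epithelial splicing regulator gene, was 5.34-fold higher (log2 ratio 2.42, 2.19 to 2.68), the desmosomal cadherin gene Dsc3 4.95-fold and Ovol1 4.84-fold. Krt18 and Itgb4 were near even, with log2 ratios of 0.04 (-0.26 to 0.33) and -0.03 (-0.27 to 0.21). Among squamous genes Tgm3 was 4.99-fold, Casp14 4.91-fold, Krt16 4.06-fold and Dsg1b 4.02-fold higher. The collagen genes Col1a2, Col6a2 and Col6a3 were 6.49-fold, 6.24-fold and 4.68-fold lower, and Twist2, an EMT transcription factor gene, 4.55-fold lower (-2.18, -2.47 to -1.94). Acta2 stood at -0.04 (-0.37 to 0.30).

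Trp63 was 2.17-fold higher (1.12, 0.94 to 1.30), Zeb1 2.04-fold lower (-1.03, -1.19 to -0.87), Vim 1.93-fold lower (-0.95, -1.17 to -0.74) and Sox2 2.07-fold lower (-1.05, -1.28 to -0.83), while Cd44 had a log2 ratio of -0.14 (-0.24 to -0.04). Bmp7 and Bmp4 were 4.03-fold and 3.41-fold higher and Ltbp2 2.60-fold lower, with a median of -0.01 over the pathway list. Lhx2 was 3.63-fold higher in a hair follicle list with a median of -0.17. Vcam1 and Itgb3 were 3.24-fold and 2.35-fold lower and Cd24a 2.37-fold higher, with a median of -0.19 over the surface markers. Axl was 2.48-fold lower among YAP/TAZ targets, whose median was -0.09, and Hmga2 2.85-fold lower among tumour stemness genes, whose median was 0.01. Over regions near gene ends Axl, Hmga2, Sox2, Ltbp2 and Itgb3 were under 2-fold, at log2 ratios of -0.45, -0.96, -0.53, -0.90 and -0.75. With the median of each chromosome set to 0, Trp63 and Cd24a were under 2-fold, at 0.80 and 0.99. Zeb1 also fell under 2-fold under at least 1 alternative. Fat2 was 2.95-fold higher, and the Fat cadherins had a median of 0.70 (percentile 98.4).

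Medians of AP-1 subunits (0.06), kinases and chromatin regulators (-0.05), housekeeping genes (-0.12) and endothelial (-0.02), melanocyte (0.71), skeletal muscle (0.19) and adipocyte markers (0.73) lay within the middle 95% of random lists, as did those of the pathway, hair follicle, surface marker, YAP/TAZ and stemness lists. Immune cell markers had a median of -0.49 (percentile 0.97), with Cx3cr1, a chemokine receptor gene of macrophages, at a log2 ratio of -1.14 (-1.60 to -0.74). Fibroblast and pericyte markers had one of -0.68 (percentile 0.11), with Dcn 2.63-fold lower, but at a log2 ratio of -0.31 over regions near its gene ends. The mesenchymal list shares Pdgfra, Lum and Dcn with the fibroblast list.

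Among the 10 genes with the largest differences on each side, not all of which are named, Glp1r was 8.86-fold, the claudin gene Cldn8 7.52-fold, the ceramidase gene Acer1 7.29-fold, the retinol acyltransferase gene Lrat 7.02-fold, Mtnr1b 6.63-fold and the desmoglein gene Dsg1c 6.57-fold higher in the library labelled Fat1 cKO Epcam-. The water channel gene Aqp1 was 13.0-fold, Foxs1 8.57-fold, Gria1 8.55-fold, Rcn3 7.54-fold and Kcna5 6.95-fold lower. Inside 1600014C10Rik, chromosome 7 from 38187775 to 38188106, the counts were 198 against 4 (log2 ratio 4.78, 3.96 to 7.23). Inside Fto, chromosome 8 from 91615592 to 91616413, they were 2 against 183 (-5.68, -9.86 to -4.93). Near Dysf, chromosome 6 from 84246292 to 84247537, they were 0 against 86. That is 35.0-fold lower with the 0 read as described above, and the log2 interval ends at -4.799.

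Of 65821 regions with enough counts in this pair, 18677 were at least 2-fold higher in the library labelled Fat1 cKO Epcam- and 12686 at least 2-fold lower, against 437 and 234 from counting error alone. If the 2 count column names were exchanged, each of these ratios would change sign.

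**Figure D3:**
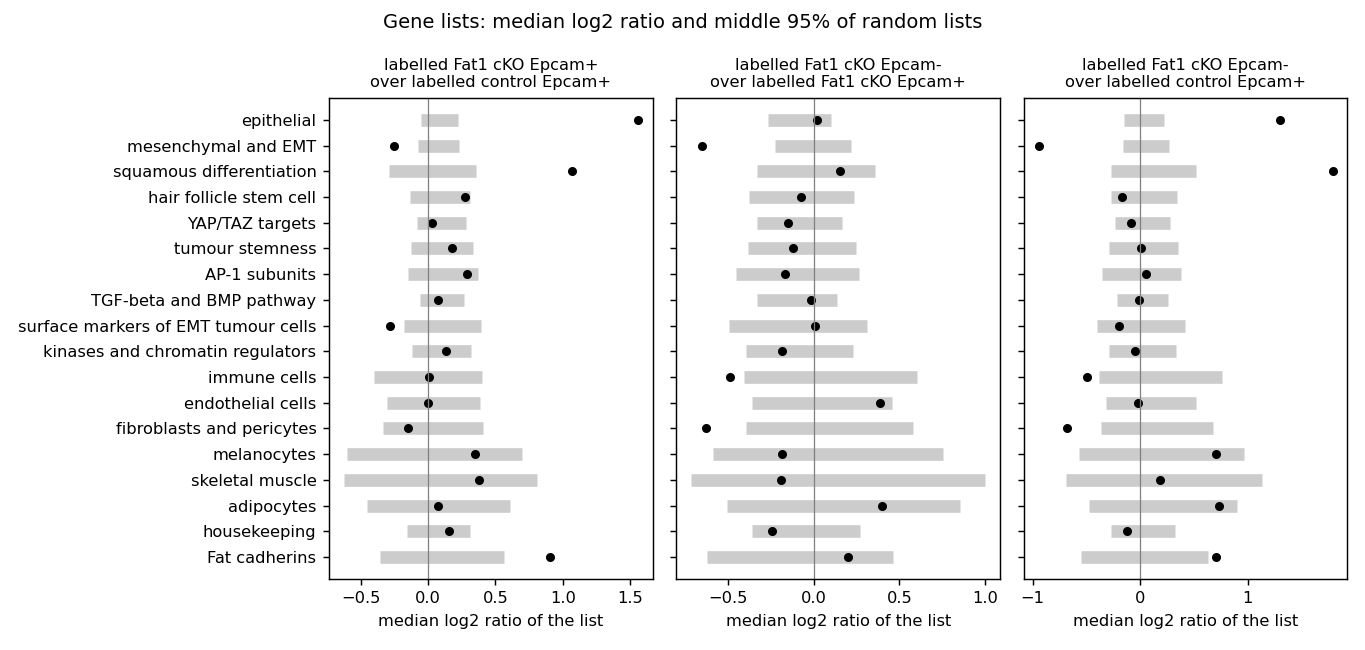
Median log2 ratio of each gene list (points, horizontal axis) in the 3 pairs of libraries, with grey bars for the middle 95% of 10000 random lists matched on mean signal. The epithelial median is 1.56 in the left panel, 0.02 in the middle and 1.30 on the right.

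The library labelled Fat1 cKO Epcam+ was then placed between the other 2. Of the 18677 regions at least 2-fold higher in the library labelled Fat1 cKO Epcam- than in that labelled control Epcam+, 22.8% were also at least 2-fold higher in the library labelled Fat1 cKO Epcam+. Of the 12686 lower regions, 42.7% were also lower there. Counting error with no difference gave 7.52% of 438 regions and 16.7% of 231. A region low in the library labelled control Epcam+ has enough counts in both ratios only if the library labelled Fat1 cKO Epcam+ is high, and only 7607 of the higher regions did. Among these the share was 55.9%, against 55.2% of only 59 regions simulated with no difference and 14.6% for independent lists. That share depends on the count minimum, so no conclusion is drawn from it. The remaining higher regions could not pass in both ratios, which also holds down the 22.8%. All 12686 lower regions had enough counts in both ratios, where independent lists would share 17.4%. Over the 69022 regions with enough counts in any library, the covariance of the 2 log2 ratios was 0.65, against 0.061 simulated. Both ratios divide by the 1 library labelled control Epcam+, so part of the excess in lower regions and in the covariance may come from that shared library. With its counts split at random between the 2 ratios, the covariance was 0.48 over 64525 regions.

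Few regions past the size rule lay near a gene end. In the library labelled Fat1 cKO Epcam+ over that labelled control Epcam+, 8.56% of higher and 6.39% of lower regions were near a gene end, against 21.8% of those considered. The shares were 7.84% and 6.18% against 19.8% in the second pair, and 8.76% and 5.25% against 18.9% in the third. Regions were not matched on signal or width. In the first pair the median width was 736 bp for higher and 724 bp for lower regions, against 880 bp of those considered. These shares therefore do not separate position from signal strength.

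Whole chromosomes stood apart in each of the 3 pairs. In the library labelled Fat1 cKO Epcam+ over that labelled control Epcam+, the median log2 ratio was 0.28 on chromosome 4 (bootstrap 95% interval over regions 0.25 to 0.32), 0.25 on chromosome 11 (0.21 to 0.28), 0.25 on chromosome 14 (0.19 to 0.29) and -0.19 on chromosome 8 (-0.22 to -0.16). In the library labelled Fat1 cKO Epcam- over that labelled Fat1 cKO Epcam+, it was 0.55 on chromosome 2 (0.51 to 0.59), -0.49 on chromosome 7 (-0.53 to -0.46), -0.32 on chromosome 6 (-0.37 to -0.27) and -0.23 on chromosome 11 (-0.27 to -0.19). In the library labelled Fat1 cKO Epcam- over that labelled control Epcam+, it was 0.52 on chromosome 4 (0.47 to 0.55), 0.49 on chromosome 14 (0.43 to 0.55), 0.45 on chromosome 2 (0.41 to 0.49), -0.31 on chromosome 7 (-0.36 to -0.27) and -0.27 on chromosome 6 (-0.32 to -0.21). The library that stood apart from both others thus differed between chromosomes. Among those listed, it was the library labelled Fat1 cKO Epcam- on chromosomes 2, 6 and 7, and that labelled Fat1 cKO Epcam+ on chromosome 11. The SD of the autosome medians was 0.14, 0.25 and 0.22 in these pairs. Genes named above on a shifted chromosome carry its shift in their ratios. On chromosome 7 these include Foxa3, Tead1, Arhgef17, Axl and Rcn3. On chromosome 2 they include Tfap2c, Bmp2, Lhx2, Fjx1 and Tgm3, and on chromosome 6 Aqp1, Col1a2 and Kcna5. In the library labelled Fat1 cKO Epcam- over that labelled Fat1 cKO Epcam+, the median of each chromosome was also set to 0. Tfap2c, Bmp2, Lhx2, Tead1 and Arhgef17 then fell under 2-fold, while Fjx1, Tgm3, Foxa3 and Col1a2 did not.

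**Figure D4:**
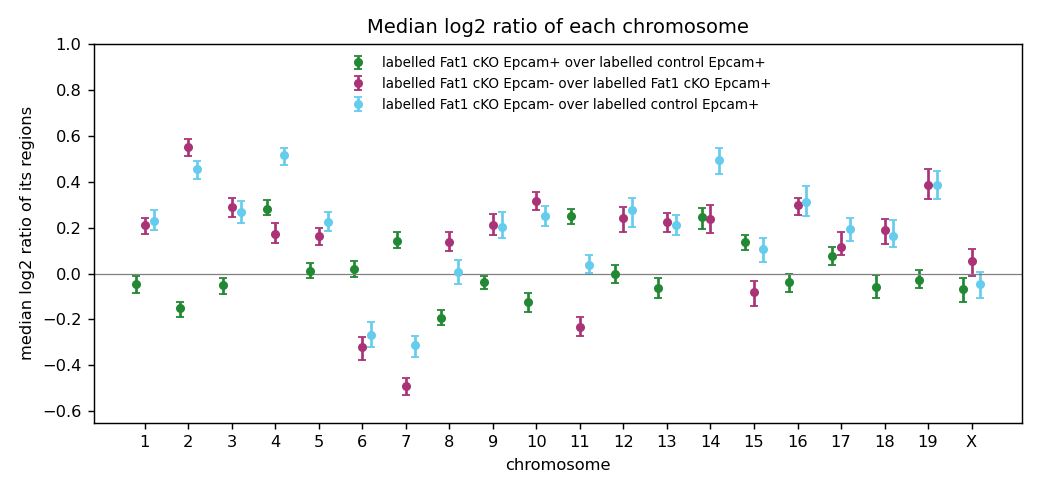
Median log2 ratio of the regions of each chromosome (vertical axis) for the 3 pairs of libraries (colours), with bootstrap 95% intervals over regions. Chromosome 7 has medians of -0.49 and -0.31 in the pairs with the library labelled Fat1 cKO Epcam- and 0.14 between the other 2, and chromosome 4 has 0.28 in the library labelled Fat1 cKO Epcam+ over that labelled control Epcam+.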

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

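The tests on the column names were chosen only after that result was seen; those on chromosome shifts and on intermediate regions were written down before their values were seen, except that the ratios of the list medians were added after. Mitochondrial regions, outside the comparisons of the report, held 39.1% of the counts in the library labelled control Epcam+, 42.6% in that labelled Fat1 cKO Epcam+ and 41.0% in that labelled Fat1 cKO Epcam-.

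The peak calls and counts of 2 libraries disagree. Lower signal over background in the library labelled control Epcam+ cannot be judged from mesenchymal and EMT genes, which are higher there. Their median log2 ratio is -0.94 for the library labelled Fat1 cKO Epcam- over that library, but lower signal would also raise regions weak elsewhere. Regions called in no library were highest there too, at a median of 1.77 CPM against 1.37 and 1.27 CPM in the others. Lower signal there is argued against by the regions called only in the library labelled Fat1 cKO Epcam-. These have a median of 5.55 CPM in the column labelled control Epcam+ and 1.82 CPM in their own. An exchange of the peak-call names alone is argued against by the epithelial list, which is higher in the library labelled Fat1 cKO Epcam- (1.30). What stays open is that the names of 2 count columns may have been exchanged: Epcam, the sorting marker, has a log2 ratio of 0.96 in favour of the library labelled Fat1 cKO Epcam- over that labelled control Epcam+, although it is lower there than in that labelled Fat1 cKO Epcam+ (-0.76), a direction that turns to 0.09 within 10 kb and over regions near its gene ends. The calls argue against a difference between sorted populations as the source, since calls and counts of 1 library come from the same cells. Of 54714 regions called under the name control Epcam+, 3563 had under 5 counts in the count column of that name. In the column labelled Fat1 cKO Epcam-, 31 had so few. Of 47604 called under the name Fat1 cKO Epcam-, 2465 had under 5 in their own column and 78 in that labelled control Epcam+. The probability that a region called under the name control Epcam+ outranked one not so called was 0.69 in its own count column. In the column labelled Fat1 cKO Epcam- it was 0.96. For calls under the name Fat1 cKO Epcam- it was 0.74 in their own column and 0.96 in that labelled control Epcam+. These values argue against calls and counts of these 2 libraries both carrying the right names. The Y chromosome counts set the library labelled Fat1 cKO Epcam- apart from the other 2, although its title names the tumour of 1 of them. They go with the exchange as well, but for them a difference between sorted populations stays untested. The mapping was left as the names give it, so the directions of the comparisons cannot be taken as those of the named cells.

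Whole chromosomes shift between the libraries, and chromosome 7 was tested. The epithelial or mesenchymal state of the cells, followed along either gene list, is argued against. Chromosome 7 was set against the other autosomes, as a shift from the library labelled control Epcam+. The shift was 0.13 in the library labelled Fat1 cKO Epcam+ and -0.55 in that labelled Fat1 cKO Epcam-. The first was -0.25 of the second (bootstrap 95% interval -0.33 to -0.18). The list medians of the same pairs have ratios of 1.20 (0.86 to 1.52) for epithelial and 0.27 (0.097 to 0.74) for mesenchymal and EMT genes, so both have the opposite sign, and a joint effect of both lists was not tested. DNA copy number could shift called and uncalled regions alike. The shift of the library labelled Fat1 cKO Epcam- from the mean of the other 2 was -0.70 in 150 regions called in no library. It was -0.57 in 4379 called ones, a ratio of 1.22 (0.87 to 1.58). The uncalled regions are also among the merged regions and hold counts, so they are not a sample of closed chromatin. A change in accessibility could shift both sets alike too, so the ratio does not separate it from copy number. Copy number stays open, as a hypothesis, and no DNA library was used here.

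Some regions that differ between the other 2 libraries differ the same way in that labelled Fat1 cKO Epcam+ (22.8% of higher and 42.7% of lower ones). The count minimum holds down the first share but not the second. A mixture of the cells of the other libraries is argued against: the share of cells like those of the library labelled control Epcam+ that it would need is 39.4% from regions higher in that library and 83.2% from regions lower there, a ratio of 0.47 (0.46 to 0.49). In addition, 4715 regions were at least 2-fold higher in the library labelled Fat1 cKO Epcam+ than in both others. A mixture with the first of these shares would give 1 by counting error alone. Variation between libraries beyond counting error is not known with 1 library per group, so no conclusion is drawn from these regions. With the exchanged names, mesenchymal and EMT genes would be higher in Fat1 cKO Epcam+ than in control Epcam+ cells (median log2 ratio 0.65), as Fat1 deletion might give, but with 1 tumour per genotype the deletion cannot be told apart from other differences between the tumours.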

How the results depend on the processing

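No paired analysis was possible because each group has 1 library. Exchanging the names of 2 count columns, an alternative chosen after seeing the data, turned or moved most of the values that answer a comparison. Under it the epithelial medians of the 3 comparisons were -0.02, -1.56 and -1.30, and the mesenchymal medians 0.65, 0.26 and 0.94, since the same libraries then carry other names. Region counts became 15597 lower in the first comparison and 8763 higher in the second, and the shared shares 38.3% of higher and 58.2% of lower regions. The count minimum and the fold limit set the counts of regions by construction. With at least 50 counts there were 4404 higher and 3075 lower in the first comparison, 6576 and 4568 in the second, and 8928 and 5410 in the third. At 4-fold there were 2767 and 2183, 4763 and 3941, and 4960 and 4876. With the whole interval past 2-fold there were 4282 and 2554, 5389 and 5628, and 7270 and 6662. With no filter on counts the lower regions were 14823, 17991 and 19342, and at 1.5-fold the lower regions of the first were 13863. The other scalings, prior counts and filters, thinning to the smallest depth included, left every count of regions within 1.5 times.

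The epithelial median of the first comparison was 1.84 over regions near gene ends. In the third, the mesenchymal median was -1.15 with the median of each chromosome set to 0 and -1.29 as a median over the regions of a gene. The shared shares of higher and lower regions were 21.0% and 32.9% with the control counts split at random between the 2 ratios, 9.9% and 21.9% at 4-fold, and 20.9% and 45.8% with total counts. Taken only from regions with enough counts in both ratios, the share of higher regions was 55.9%, a value that depends on that count minimum. Over regions near gene ends, the surface markers of EMT tumour cells turned to 0.13 in the first comparison and fibroblast and pericyte markers to 0.27 in the second. In the second comparison Epcam turned to 0.09 both there and within 10 kb, and Cd44 to -0.04 near gene ends. With the median of each chromosome set to 0, Cd44 turned to -0.33 and Trp63 to -0.08 in that comparison. The cause was not tested for these. Of 465 combinations of gene and comparison under the naming rule, 27 were counted as changing sign under at least 1 alternative of scaling or gene assignment. Among the 131 described, 3 were. These counts are too low, since they left out some genes near even. Cldn1 went from 0.16 to -0.10 in the first comparison as a median over its regions. Itgb4 went from -0.03 to 0.24 in the third over regions near its gene ends. The size of the described ratios depends more on the settings: 85 left their counting interval under at least 1 alternative, 73 of them under another way of assigning or combining the regions of a gene, and 39 moved by over 1.5 times, farthest under such a setting in each case. Of 108 described as at least 2-fold apart, 26 fell under 2-fold under at least 1 alternative. These cover genes, not single regions. The correction for GC content and the alternatives for motif shares were not run.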

Other observations

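Krt18 had 38.8 CPM in the library labelled control Epcam+, 144 CPM in that labelled Fat1 cKO Epcam+ and 39.8 CPM in that labelled Fat1 cKO Epcam-, and Krt8 had 26.8, 102 and 31.8 CPM. The basal keratin genes Krt14 and Krt5 had 22.4, 122 and 71.6 CPM and 15.1, 78.2 and 50.4 CPM in the same order. These 4 keratin genes, set side by side after their values were seen, were each highest in the library labelled Fat1 cKO Epcam+. Bmp4 was lowest in the library labelled Fat1 cKO Epcam+, at 9.57 CPM against 18.9 and 65.3 CPM, whereas Bmp7 was at 237 CPM there, 57.0 CPM in that labelled control Epcam+ and 231 CPM in that labelled Fat1 cKO Epcam-.

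With at least 20 counts in both others, 2168 regions were at least 2-fold lower in the library labelled Fat1 cKO Epcam+ than in both others.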
